A study of Drosophila melanogaster with 2 samples.

How the data were processed

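Both samples were whole embryos of a transgenic line with an insertion of a GFP-tagged ranshi gene, collected at 0 to 24 h. Chromatin was sheared by sonication to a size range of 200 to 800, and an anti-GFP antibody was used for the immunoprecipitation, per the labels. The labels name them as biological replicates 1 and 2 of 1 group, and the grouping was taken from there. Control libraries were not analysed here.

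The files were 8 peak lists on assembly dm6. For each replicate there was a list of ranked candidate peaks and a thresholded set, and for the series a conservative set, a larger thresholded set and the ranked list behind each. The aligner, the peak caller and their versions are not given in the sources used here. The deposited score of each peak is a whole number up to 1000. On the ranked lists it matched 125 times the binary logarithm of the inverse irreproducible discovery rate (IDR), within 1 unit, for 100% of peaks. Every thresholded set had a minimum score of 830, which corresponds to a global IDR of 0.01. The global IDR is the estimated share, among peaks at a given rank or better, that would not recur in a repeat. The deposited signal of each peak is the peak caller's own value and is not scaled between lists, and apart from the correlation between replicates, on log2 values and on ranks, it was used within a list. The deposited −log10 values hold the q-value of the peak and, in the ranked lists, its IDR, and were used to describe the lists. Summit positions came from the deposited offsets. Per the file contents, the conservative set was a subset of the first series ranked list, and the sets left out some peaks that passed the score limit, 69 in the conservative case. In the 2 series ranked lists, columns of values for the separate inputs were not matched to a sample and were not used (4 such kinds of column).

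Gene models came from the Ensembl release 115 annotation and sequence from the RefSeq assembly of the same build. All 428083 peak records on the 7 assembled arms ended within the arm lengths, with 0 beyond. Transposable element genes and starts of pseudogenes were left out. Peaks on other sequences were left out of annotation, which concerned 14 peaks of the larger set and 54 of the replicate 1 set. A promoter was defined as the 500 bp to each side of a transcript start, and the remaining summits were assigned to 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic, in that order. The non-coding exon class was added after the plan was fixed.

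Peak lists were compared by overlap of 1 bp or more, with chance from 1000 draws of candidates and 1000 random placements within arms. Shares were given with exact or Wilson binomial 95% intervals, which cover counting error only. The background for promoter, feature and chromosome shares was every candidate of the set's own ranked list that overlapped no thresholded peak. Shares were tested with Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over 7 feature classes and over 30 gene lists. The gene lists were fixed before the data were examined, and 7 members were matched through older symbols. In 8 lists, 9 names had no unique match and were left out, among them phm, nos and Dl, and 4 names were of a gene already listed. In the glycolysis list the unmatched name was Ald, an older symbol of the listed gene Ald1. List members and all other protein-coding genes entered a test where a candidate lay within 500 bp of a start. Signals were compared by a permutation test on medians with 100000 resamples. Canonical words of 6, 7 and 8 bases were counted in 101 bp around summits and in windows 300 bp to each side, found in odd-numbered and tested in even-numbered peaks in chromosomal order, with the smaller tail of Fisher's exact test doubled.

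The named genes followed a rule fixed before the data were examined: ranshi, ouib, nom, trem and CG8159, the closest gene of the 20 highest conservative peaks, up to 3 members of highest signal per gene list, and the 3 highest peaks farther than 5 kb from a start. M1BP entered as a list member and CG8202 was named after its value was seen. Alternatives fixed beforehand changed the peak set, the replicate, the promoter window, the background, the assignment of genes, the motif window and the rule for overlap. The search for words of 9 bases and the weight matrix, fitted by expectation maximisation in 80 steps, their alternatives and the backward matrix were chosen after seeing the data.

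Parts of the steps were tested on simulated data. The share test called 4.90% of 2000 null draws and 100% of 200 draws with a share raised from the background. For the word counts, a planted word among 32896 words was recovered, with 14 words called including its overlapping neighbours. Without it, 0 were called. That simulation used the longest words in flank windows, so a difference in base composition between summits and flanks was not simulated. Its 0 calls therefore give no rate of false calls for words that follow base composition. For the weight matrix, 100% of 461 planted sites and 0.194% of the other windows passed a fixed score limit. The matrix was started from part of the planted site and scored on the windows it was fitted to. The search for a leading word and the limit set from flanks were therefore not tested. With 2 samples in 1 group, no test across samples was possible. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.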

Results

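Chromatin immunoprecipitation followed by sequencing measured where a ranshi-eGFP fusion protein lay on the genome of whole Drosophila melanogaster embryos aged 0 to 24 h. The ranshi gene encodes a zinc finger protein of the ZAD family, a class of zinc finger proteins that is large in insects, and the fusion was pulled down through its GFP tag. The design held 1 group of 2 biological replicates, and no second group was compared, so the design implies how far the replicates gave the same sites and where those sites lay. Read depth was not given in the sources used here. Replicate 1 had 112688 ranked candidate peaks, of which 3636 were in its thresholded set, and replicate 2 had 83284 candidates and 3149 thresholded peaks. Across replicates, the conservative set held 2984 peaks with a median width of 316 bp and a median signal of 137 (range 2.16 to 2765), and a larger thresholded set held 5373 peaks.

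The tagged gene was examined first. The only conservative peak within 5 kb of ranshi (dm6 3R:8728367-8729693, minus strand) was at 3R:8731939-8732106, with its summit 2308 bp upstream of the start of ranshi, a signal of 311 and rank 433 of 2984. It lay in intergenic sequence between M1BP, another ZAD family gene whose product binds the core promoter element Motif 1, and CG8202. The summit was 90 bp from a CG8202 start and 303 bp from the start of M1BP. Both replicates had a thresholded peak there, with a signal of 237 (rank 346) in replicate 1 and 46 (rank 2102) in replicate 2. The larger set added a peak in an intron inside M1BP, at 3R:8730455-8730770, 920 bp upstream of the start of ranshi, with a signal of 62.6. No conservative peak lay within 5 kb of the paralogues ouib or nom, and the peak between M1BP and CG8202 was also the single one within 5 kb of CG8159. At trem, a more distant ZAD gene that acts in meiosis, a conservative peak at 3R:20031215-20031530 had its summit 64 bp from the trem start, with a signal of 82.6 and rank 2525. It was in the thresholded set of replicate 1 and not in that of replicate 2. In all, 3 conservative peaks lay within 5 kb of trem. The others, at 3R:20031460-20031775 (signal 73.7) and 3R:20035996-20036311 (signal 159), were closer to starts of other genes.

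The 20 peaks of highest signal ran from 1236 to 2765, and 15 of them lay within 500 bp of a transcript start. All 20 were in the thresholded sets of both replicates. The highest was 43 bp from the start of Ugalt, which encodes a UDP-galactose transporter, in intergenic sequence at X:2703720-2704051. It was followed by the promoter of CG14100 at 3L:19590461-19590771 (signal 2481) and an intronic peak 1026 bp from a start of CG11050 at 2L:6612555-6612887 (signal 2129). Mitochondrial functions were represented by mRpL41, a mitochondrial ribosomal protein gene (signal 1954, rank 4, 133 bp from the start), and by PNPase, a mitochondrial RNA exonuclease gene (signal 1618, rank 8, in the 5' UTR). Chromatin genes in this group were ph-p, a Polycomb group gene (signal 1699, rank 7), and Chro, whose product binds interbands of polytene chromosomes (signal 1346, rank 14). The others were CG7601, Tcs5, asRNA:CR45928, CenG1A, Adf1, CG5611, Art3, CG32772, px, CG13323, CG9147, lncRNA:CR45643 and CG13390, with signals from 1236 to 1780.

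Of the peaks farther than 5 kb from any transcript start, the highest was intergenic at 2R:13035212-13035465, 11909 bp from CG13323, with a signal of 1262 and rank 17. An intronic peak 5716 bp from the closest start, that of CG16753, had a signal of 987 at 3L:3060666-3060917. Another intronic peak lay 7898 bp from a start of Hr3, a nuclear receptor gene induced by ecdysone, at 2R:10219947-10220192, with a signal of 712. In all, 459 conservative peaks (15.4%) lay farther than 5 kb from a start.

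The replicates shared a large part of their sites. Of the replicate 1 peaks, 1763 of 3636 overlapped a replicate 2 peak by 1 bp or more (48.5%, 95% Wilson interval 46.9 to 50.1). Of the replicate 2 peaks, 1791 of 3149 overlapped a replicate 1 peak (56.9%, 55.1 to 58.6). In 1000 draws of as many peaks from the other replicate's candidates, the highest shared share was 4.92% for replicate 1 and 3.43% for replicate 2. In 1000 random placements within chromosome arms the highest shares were 1.87% and 2.19%. Candidates of the other replicate covered more: 93.0% of the replicate 1 peaks overlapped a replicate 2 candidate, against 75.3% in the other direction, which left 777 replicate 2 peaks without any replicate 1 candidate. Across 4514 peaks of the larger set matched in both candidate lists, the log2 signals had a Pearson r of 0.55 and a Spearman rho of 0.505. These are values across peaks, which are not independent replicates, and the conservative set gave an r of 0.72.

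The conservative set was nested in the larger set for 97.2% of its peaks (95% interval 96.6 to 97.8). It overlapped the replicate 1 set at 86.5% and the replicate 2 set at 65.5% of its peaks. The larger replicate set had 1.15 times as many peaks as the smaller one, and the larger series set 1.80 times as many as the conservative set.

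Summits were concentrated just upstream of transcript starts and were nearly absent from coding sequence outside promoter windows. Of the 2984 conservative summits, 1425 lay within 500 bp of a start (47.8%, exact 95% interval 45.9 to 49.6), against 14.5% of 83283 candidates that entered no thresholded set (odds ratio 5.39, 95% interval 5.0 to 5.80, Fisher's exact test). Of these promoter summits, 1175 were upstream of the closest start (82.5%, exact 95% interval 80.4 to 84.4), with a median position of -107 bp and an interquartile range from -185 to -36 bp. Coding exons outside promoter windows held 12 summits (0.402%, 0.208 to 0.701), against 23.5% of the candidates (odds ratio 0.0131, 95% interval 0.00785 to 0.0238). The coding exon odds ratio was 0.0288 in replicate 1 alone, 0.0437 in the larger set and 0.0255 against random positions. The 3' UTR share was 0.670% against 2.32% (odds ratio 0.284, adjusted p 1.33e-11), and the 5' UTR share outside promoter windows was 0.402% against 1.07% (odds ratio 0.372, adjusted p 1.52e-04). Introns held 35.9% of summits against 37.8% of candidates (odds ratio 0.920, adjusted p 0.0366), and intergenic sequence 13.7% against 19.8% (odds ratio 0.645, adjusted p 3.75e-17). Non-coding exons did not pass the test (1.14% against 0.938%, adjusted p 0.248). Peaks are not replicates, so these p-values cover counting error only. The promoter share was 44.0% in replicate 1 alone (42.4 to 45.6) and 55.4% in replicate 2 alone (53.6 to 57.1).

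**Figure D1:**
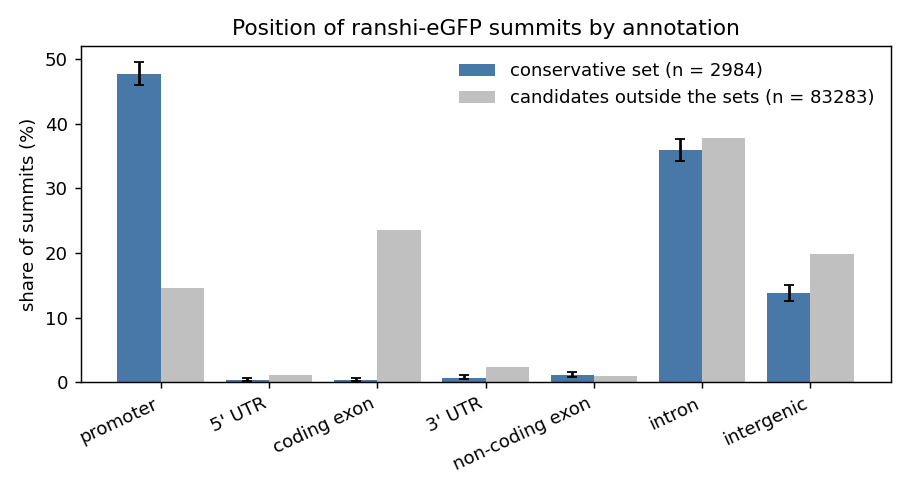
Share of summits (%) in each annotation class for the 2984 conservative peaks (blue, bars with exact 95% intervals) and for 83283 candidates outside the thresholded sets (grey). Promoter windows hold 47.8% of the conservative summits against 14.5% of the candidates, and coding exons outside these windows 0.402% against 23.5%.

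**Figure D2:**
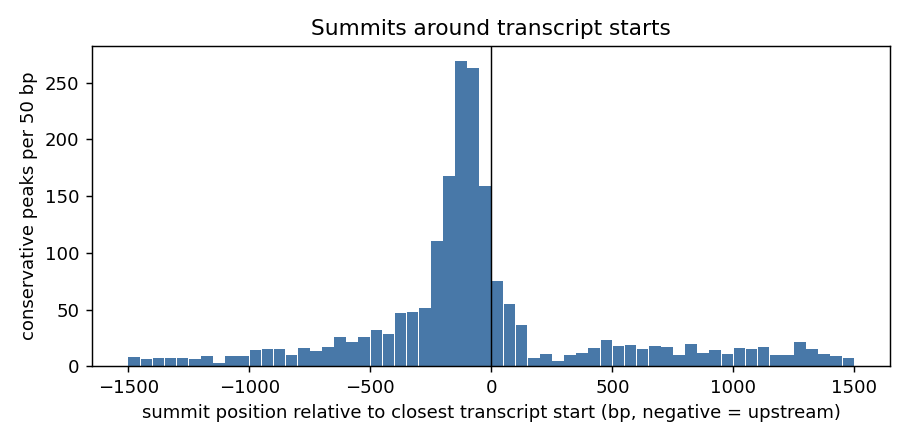
Number of conservative summits per 50 bp against their position relative to the closest transcript start in bp, with negative values upstream. The summits gather upstream of the start, with a median of -107 bp among those within 500 bp.

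Cytoplasmic ribosomal protein genes and glycolysis genes carried peaks more often than other genes. Of 8240 protein-coding genes with a candidate within 500 bp of a start, 1778 had a conservative peak there. Cytoplasmic ribosomal protein genes had one at 42 of 68 tested members (61.8%), against 21.2% of the other genes (odds ratio 5.99, 95% interval 3.65 to 9.68, adjusted p 2.32e-11, Fisher's exact test over 30 lists). RpL32 had the highest signal among them (534, rank 142), followed by RpL7 (469) and RpS21 (427). The share held in each replicate alone, at 62 of 84 tested members in replicate 2 (odds ratio 12.1, 95% interval 7.35 to 19.4) and 42 of 66 in replicate 1 (odds ratio 5.84). Glycolysis genes had a peak at 7 of 9 tested members, with Gapdh2 (glyceraldehyde-3-phosphate dehydrogenase, signal 823), Eno (enolase, 396) and Ldh (lactate dehydrogenase, 239) the highest (odds ratio 12.8, adjusted p 0.00384, Fisher's exact test). Few genes lay behind that call. It did not pass in replicate 2 alone, with 5 of 12 (adjusted p 0.167, Fisher's exact test). Nor did it pass with windows of 200 bp, with 5 of 9 (adjusted p 0.126, Fisher's exact test).

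Receptor, cuticle and transfer RNA genes carried fewer peaks than other genes. None of 71 odorant and gustatory receptor genes had a peak (0 of 71, which allows a share of up to 4.23%; adjusted p 6.48e-07), nor did any of 63 cuticle protein genes (0 of 63, up to 4.76%; adjusted p 2.80e-06). Transfer RNA genes had a peak at 7 of 80 (8.75%, odds ratio 0.349, adjusted p 0.0224), with tRNA:Tyr-GTA-1-8 the highest (signal 451). By closest gene the transfer RNA share was 12.7% and did not pass (adjusted p 0.209). These families were measured against the same 21.6 to 21.8% of other genes.

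The other 25 lists did not pass the test in the conservative set. Mitochondrial ribosomal protein genes had peaks at 16 of 48 members (33.3%, adjusted p 0.177). They passed in the larger set, with 28 of 69 (adjusted p 0.0355), and in replicate 1 alone, with 17 of 41 (adjusted p 0.0455), whereas replicate 2 alone gave 17.4% (odds ratio 0.877). The genes mRpL41, mRpS23 (signal 1514) and mRpS10 (signal 1392) were within 500 bp of peaks that ranked in the top 20. Insulator protein genes had peaks at 5 of 9 members (adjusted p 0.115, Fisher's exact test), among them Chro, Cp190 (signal 436) and Trl (signal 246), which encodes the GAGA factor. With windows of 200 bp the insulator list passed (71.4%, adjusted p 0.0438, Fisher's exact test). Heat shock genes had 6 of 13 (adjusted p 0.158), led by Hsp27 (signal 719), Hsp83 (signal 301) and Hsc70-4 (signal 259). ZAD zinc finger genes had 5 of 11 (adjusted p 0.201), among them M1BP, Sry-delta (signal 193) and prg (signal 109). Translation factor genes had 12 of 36 (adjusted p 0.279), with eIF6 at 1527 and eEF1gamma at 327. Genes of ecdysteroid biosynthesis had 0 of 7 (which allows a share of up to 42.9%; adjusted p 0.582, Fisher's exact test), and genes of the ecdysone response had 3 of 10 (adjusted p 0.613), which were E23 (signal 490), Eip75B (172) and Hr78 (93.6). The ecdysone response list passed in the larger set, with 9 of 13 (adjusted p 0.00656), and in replicate 2 alone, with 7 of 14 (adjusted p 0.0411). Small nucleolar RNA genes had 11 of 93 (11.8%, adjusted p 0.109) and passed as lower in the larger set (10.6%, adjusted p 3.08e-05) and in replicate 2 alone (9.04%, adjusted p 0.00123), but not in replicate 1 alone (16.7%, adjusted p 0.606), and windows of 1000 bp gave 27.9% (odds ratio 1.34, adjusted p 0.358).

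Lists of body patterning and single-tissue genes did not pass either, and their counts were small. Segmentation genes had 1 of 15 members with a peak (bcd, signal 147), neural genes 1 of 16 (elav, signal 516), Hox genes 1 of 5 (Dfd, signal 87.5) and tracheal genes 1 of 7 (trh, signal 171). Muscle genes had 3 of 14 (tin, 476; Msp300, 335; sls, 202), gut and fat body genes 1 of 13 (fkh, signal 186), and yolk and haemocyte genes 0 of 7. Their adjusted p-values ranged from 0.472 to 1.

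Peaks on the X chromosome did not stand apart from the candidates in the conservative set. Its share was 609 peaks (20.4%) against 20.1% of candidates (odds ratio 1.02, 95% interval 0.934 to 1.12, p 0.642, Fisher's exact test). The replicates went opposite ways. In replicate 1 the X share was 20.6% against 16.9% of its candidates (odds ratio 1.28, p 1.48e-08), and in replicate 2 it was 15.8% against 18.1% (odds ratio 0.851, p 0.00101, Fisher's exact test). Density on the major arms ran from 20.3 peaks per Mb on 2R to 25.9 on X, and chromosome 4 held 1 conservative peak.

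Promoter peaks were higher than others in the conservative set, with a median signal of 160. The ratio of medians, 1425 promoter peaks over 1559 others, was 1.28 (bootstrap 95% interval 1.2 to 1.36), and the 2-sided permutation p was 1e-05, the smallest that 100000 resamples can give. Replicate 1 alone gave a ratio of 1.34 and replicate 2 alone 0.991 (p 0.541), so the difference was not seen in replicate 2.

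Sequence at the summits was rich in A and T. In windows centred on summits, mean G+C was 33.3% ± 9.73 (SD across 2984 peaks) at conservative summits and 44.1% ± 9.89 in windows 300 bp to each side, whereas candidates outside the sets had 47.8% ± 9.52 at their summits. Of 43168 canonical words of 6 to 8 bases, 1437 were more frequent at summits than in flanks in the odd-numbered peaks, and 1083 of these also passed in the even-numbered peaks. Among those 1083 words, 914 held at most 1 G or C. The word ATATTTTA was present in 97 of 1492 summit windows (6.50%) against 1.41% of flanks (adjusted p 2.78e-17), a fold of 4.62 that was 1.86 in replicate 2 alone (adjusted p 2.18e-04). The 16 fixed motifs included promoter and insulator elements and sites of other transcription factors. Of these, 11 passed, 7 of them more frequent at summits and 4 less. The TATA box consensus was at 9.05% of summits against 3.55% of flanks (adjusted p 2.81e-12), the homeodomain core TAATTA at 10.1% against 4.79% (adjusted p 8.26e-10), and DRE, a core promoter element, at 2.88% against 1.14% (adjusted p 2.25e-04). In replicate 2 alone the TATA box fold was 1.43 instead of 2.55 (adjusted p 0.0177). The GATA site (fold 1.32, adjusted p 1.05e-04), the BEAF-32 core and the Initiator (both adjusted p 0.00163) and Motif 7 (fold 1.88, adjusted p 0.0286) were also more frequent. DRE did not pass in replicate 1 alone (fold 1.56, adjusted p 0.0944). The GAGA consensus was less frequent, at 1.14% against 3.65% (adjusted p 2.53e-06), as was the E-box CAGCTG (2.55% against 4.99%, adjusted p 2.36e-04). The E-box CACGTG (fold 0.429) and the TCT initiator (fold 0.806) were less frequent as well (both adjusted p 0.0286). Of these 11 motifs, the TATA box, the homeodomain core and the GATA site passed under every alternative and the others did not: the GAGA fold was 0.905 against candidates (adjusted p 0.853) and 0.673 in replicate 2 alone (adjusted p 0.0815), and the E-box CAGCTG did not pass in the larger set (adjusted p 0.0598) and turned to a fold of 1.1 in replicate 2 alone (adjusted p 0.619). Motif 1, the element bound by M1BP, did not pass (0.268% against 0.168%, adjusted p 0.746), but passed in the larger set (fold 4.5, adjusted p 0.0312), in replicate 2 alone (fold 6, adjusted p 0.0177) and in wider windows (fold 2.89, adjusted p 0.0406). Few windows lay behind these folds: 9 of 2679 summits against 4 of 5358 flanks, 9 of 1574 against 3 of 3148, and 13 of 1492 against 9 of 2984. Motif 1 did not pass in replicate 1 alone (fold 1.5), the higher-signal peaks (fold 0.667), 51 bp windows (fold 4) or against candidates (fold 3.85). Base composition was not matched for any motif of the panel. This limit holds for consensus sites with many A and T bases and for the motifs that were less frequent at the A+T-rich summits.

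**Figure D3:**
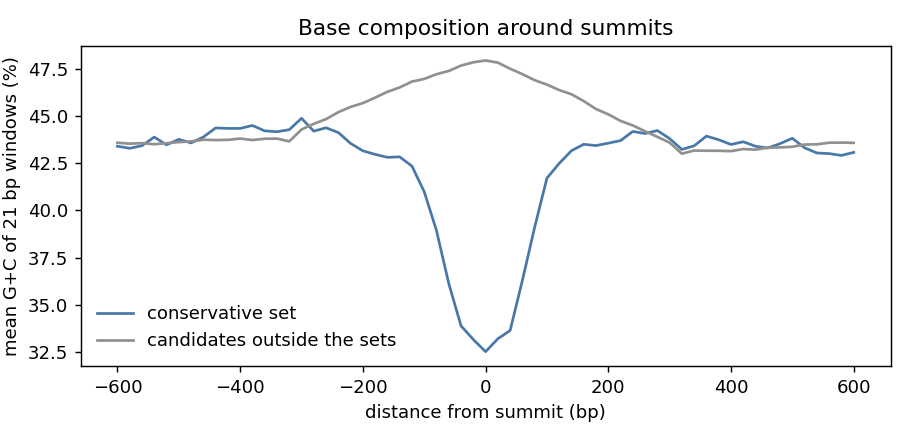
Mean G+C (%) of 21 bp windows against distance from the summit in bp, for the conservative set (blue) and for candidates outside the thresholded sets (grey). G+C falls to 32.5% at conservative summits and reaches 47.9% at candidate summits.

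A search for longer words was added after the data were examined. Words of 9 bases within 150 bp of summits were set against windows 700 bp away and against the same word read backwards, which has the same bases. Of the 20 leading words from the odd-numbered peaks, 18 passed in the even-numbered peaks, and 15 held the core CACTG. CACTGAGAG was near 55 of 1492 summits (3.69%) against 6 of 2984 flanking windows (0.201%, adjusted p 3.23e-19), and its backward form was near 2. CCACTGTGC was near 77 summits against 29 flanking windows, and CTATCGATA, which contains the DRE core, near 45 against 14. A weight matrix of 19 positions built from the odd-numbered peaks had the consensus AAGTACACTGAGAGAAAAA. At a score passed by 5% of the flanks of those peaks, it was found near 434 of the 1492 held-out summits (29.1%, exact 95% interval 26.8 to 31.5) and in 3.62% of their flanks (odds ratio 10.9, p 4.47e-127, Fisher's exact test). Read backwards, which keeps its base composition, the matrix was near 3.55% of the same summits (exact 95% interval 2.67 to 4.62) and in 5.13% of their flanks, at a limit set in the same way. The share depends on the score limit, and at a score passed by 1% of the discovery flanks it was 12.3%. Odd- and even-numbered peaks were not filtered for overlap with each other, for the matrix or for the words. The 2984 conservative peaks form 2883 merged regions, so some held-out windows share sequence with discovery windows. Each replicate alone was scored on its peaks that did not touch the odd-numbered peaks. The motif was near 30% of 2287 such peaks in replicate 1 and 15.1% of 2146 in replicate 2. These are not shares of the whole replicate sets. The conservative peaks behind the matrix overlapped the replicate 1 set more often than the replicate 2 set, so the comparison may lean towards replicate 1.

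This CACTG motif was more frequent away from promoters. It was near 319 of 770 held-out summits outside promoter windows (41.4%) and 15.9% of 722 within them (odds ratio 3.73, 95% interval 2.91 to 4.76, p 5.13e-28, Fisher's exact test). Their flanks differed too, at 4.87% and 2.29%, and against their own flanks the odds ratios were 13.8 and 8.10. Among 235 held-out summits farther than 5 kb from a start, 48.9% had it (42.4 to 55.5). Of the 20 highest peaks, 15 of them at promoters, 2 had it: the intergenic peak closest to CG13323, with the site CCACACACTGGGGGAAAAG at 2R:13035258-13035276, and the promoter peak at px, a wing vein gene, 199 bp from a start, with GCGTACACTGTGGAAAAAT at 2R:22514216-22514234. Summits lay on the 3' side of the motif in 405 of the 434 cases (93.3%, exact 95% interval 90.5 to 95.5), at a median distance of 73.5 bp (interquartile range 50 to 91.8).

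**Figure D4:**
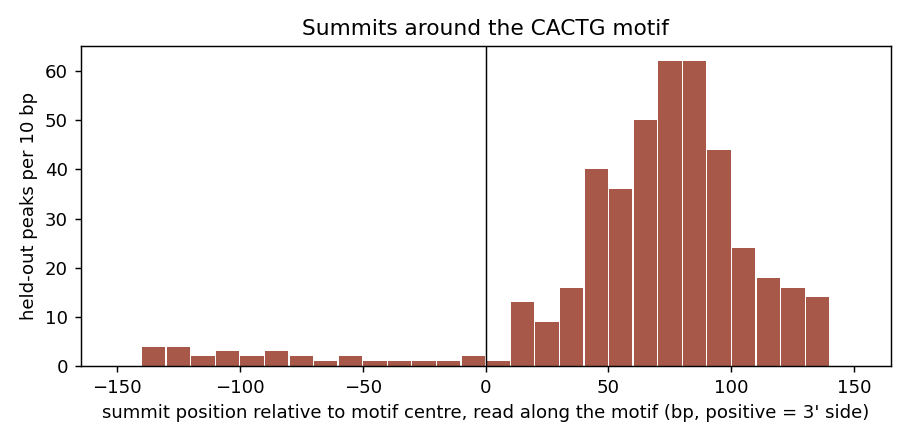
Number of held-out conservative peaks per 10 bp against the position of the summit relative to the centre of the CACTG motif in bp, read along the motif. Of 434 summits, 405 lie on the 3' side, with a median distance of 73.5 bp.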

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

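The tests of a caller shift and of G+C-dependent yield were chosen after the results were seen, as was the CACTG motif itself. The tests of A+T-rich sequence, of weak peaks and of motif content in matched peaks were set before their results were seen.

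The sets leave out peaks that pass the score limit. Of the ranked peaks behind the conservative set, 69 passed the limit and were not in it, 40 of them on 3R and 21 on 2L. Their median signal was 152, against 137 for the peaks kept, and 36 lay within 500 bp of a transcript start. A further file went into the thresholded sets, its contents not being given in the sources used here, so why these peaks were left out is not known. The highest, chosen after its value was seen, was in an intron 1399 bp from a start of cbt, a zinc finger transcription factor gene, at 2L:480926-481243, with a signal of 1911 that would rank 5. It was followed by an intronic peak 966 bp from a start of Lk6, a kinase gene (3R:11760903-11761176, signal 1377). The next was a promoter peak by the 500 bp rule, in an intron 345 bp from a start of larp, an RNA-binding protein gene (3R:28326461-28326738, signal 974).

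Replicate 1 had 54 thresholded peaks on 48 sequences outside the assembled arms, with a median signal of 57.8 against 79.8 on the arms, whereas replicate 2 had 0. Its ranked list had 483 candidates on Y against 4 in replicate 2. On chromosome 4 the order was the other way, with 44 candidates in replicate 1 and 467 in replicate 2.

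Summits lay to the 3' side of the CACTG motif. A shift between strands in peak calling would move summits without regard to the motif's orientation and give about equal numbers on each side, and the observed 93.3% (exact 95% interval 90.5 to 95.5) argues against it. Sequence composition stays open: G+C averaged 29.1% on the 3' side of the motif, from 20 to 120 bp, and 47.2% on the 5' side. At the 23 motifs whose 5' side had less G+C, 56.5% of summits were on the 3' side (exact 95% interval 34.5 to 76.8), against 95.4% at the others. These 23 motifs are too few to decide whether the summit may follow A+T-rich sequence or the motif. No biological explanation for the side of the summits was tested.

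Of the replicate 2 peaks, 777 had no replicate 1 candidate. They were weaker than the other 2372, with a median signal of 46.3 against 57.7 (ratio 0.803, bootstrap 95% interval 0.774 to 0.824), so low signal may account for part of the gap. They were also richer in G+C at the summit, with 43.2% ± 10.4 against 35.8% ± 10.9 (SD across peaks). Whether the replicate 2 library gave a higher yield from G+C-rich sequence stays open, since the lists went opposite ways. Its candidates held less G+C than those of replicate 1, by a difference of -0.62 percentage points (95% interval -0.71 to -0.53), or -0.961 in equal numbers of the highest candidates (-1.06 to -0.865). Its thresholded peaks held more, by 5.06 points (4.56 to 5.56). Matched on signal in 5 groups, the motif was less frequent in the peaks without a candidate, by a difference of -11.5 percentage points (bootstrap 95% interval -14.5 to -8.66), so signal as deposited did not account for the difference in motif content. Before matching, the shares were 6.67% of 765 peaks without a candidate and 19.8% of 1381 with a candidate, none touching the discovery peaks. The 1261 such peaks outside the replicate 1 set, which include those 765, had the motif at 6.82%. A low share was thus not particular to peaks without a candidate. The matrix came from conservative peaks, so low shares among replicate 2 peaks outside the replicate 1 set may be partly built in.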

How the results depend on the processing

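Of 59 alternatives to the main results, 40 were labelled as the same. That label meant the same call, or a value within the main interval. For numbers of classes, gene lists, words and locus peaks it meant a count within a fixed ratio of the main count, whichever members passed. The promoter share stayed past the threshold under every alternative. So did the share and side of the CACTG motif, whose alternatives were chosen after seeing the data. The motif share moved to 15.1% in replicate 2 alone, among 2146 peaks that did not touch the discovery peaks. From 5 to 6 feature classes passed, and introns did not in the larger set (adjusted p 0.0580). From 5 to 7 gene lists passed, and not always the same ones: glycolysis did not pass in the larger set (58.3%, adjusted p 0.0655). The promoter share ran from 34.6% with 200 bp windows to 58.7% with 1000 bp windows.

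The X share was 20.4% and past the threshold against arm length (p 7.19e-05). Leaving out each replicate gave 15.8% to 20.6%, past the threshold in opposite directions. The promoter signal ratio was 0.991 to 1.34 when a replicate was left out. The number of words that passed was 126 to 1670 without a replicate, 415 in 51 bp windows, 1777 in the wider windows and 2714 against candidates; the window length and background set how many words can pass, and otherwise the cause was not tested. The shared share of replicate 1 peaks was 39.8% at 50% reciprocal overlap and 58.1% among the higher-signal peaks of each replicate. For replicate 2 peaks these were 46.2% and 67%, and 54.2% with summits within 100 bp. Nesting was 95.5% under both stricter rules. The correlation was 0.72 in the conservative set and 0.59 with summits within 100 bp. Within 20 kb of ranshi there were 3 conservative peaks. These comparisons of lists have no value with a replicate left out, and no paired analysis was possible because there is 1 group.

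Among single gene lists, classes and motifs, 331 of 382 alternatives gave the same call. The direction turned in 39, in 33 of them with no call on either side and in 6 with a call on at least 1 side, the cause not being tested. Of those 6, signalling genes reached 38.9% in replicate 2, 19.2% in replicate 1 and 39.4% by closest gene, and histones 0.870% against all genes. The E-box CAGCTG fold was 1.1 in replicate 2 and 0.633 in replicate 1, Motif 7 0.941 in the higher-signal peaks and the TCT initiator 1.07 against candidates.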

Other observations

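The tests in this part were set before their results were seen, except the motif shares of the unshared and larger-set peaks and the orientation count, which were chosen after the CACTG motif had been found.

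The CACTG motif was near a larger share of the unshared peaks of replicate 1 than of those of replicate 2. Among peaks that did not touch the discovery peaks, it was near 31.7% of 1418 replicate 1 peaks outside the replicate 2 set and near 6.82% of 1261 replicate 2 peaks outside the replicate 1 set (odds ratio 6.35, 95% interval 4.95 to 8.08, Fisher's exact test). Each side was a single library, so this interval covers counting error only. The matrix was built from conservative peaks, which overlapped the replicate 1 set at 86.5% and the replicate 2 set at 65.5%. Part of the difference may therefore be built in, and how much was not tested. Replicate 1 peaks shared with replicate 2 had the motif at 27.3%. In replicate 2 the words ATCGATAG, which holds the DRE core, and CAACACTG led the words of 8 bases, at 2.41% of summits against 0.413% of flanks and 1.78% against 0.191%. Peaks of the larger set outside the conservative set had the motif at 20.3%, against 4.12% of their flanks. At promoters, 39.1% of motifs were on the strand of the closest gene (exact 95% interval 30.2 to 48.7).

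A hypothesis that ribosomal protein promoters carry peaks through a higher CACTG motif content was tested. None of 21 held-out peaks at these promoters had the motif, against 16.4% of 701 at other promoters (odds ratio 0, p 0.0355, Fisher's exact test). The direction was the opposite of the one tested. The test set beforehand asked for an interval wholly below 1.5 to argue against the hypothesis, and with so few peaks the interval extended beyond that bound, so the question stays open.

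A second hypothesis was that peaks with the motif are higher. The median signal was 134 in 434 held-out peaks with the motif and 140 in 1058 without it. The ratio was 0.960 (bootstrap 95% interval 0.889 to 1.04, permutation p 0.350), so no higher signal was found across promoter and other peaks together. Promoter class was not matched in this comparison. The motif was near 15.9% of held-out promoter peaks and 41.4% of the others. Promoter peaks of the conservative set were higher, with a ratio of medians of 1.28. Whether peaks with the motif are higher within either class was not tested. Among 5 groups by signal, the motif was near 30.4% of the lowest peaks and 23.7% of the highest.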
